A study of Chlamydomonas reinhardtii with 8 samples.

How the data were processed

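The series holds RNA sequencing of the unicellular green alga Chlamydomonas reinhardtii, strain CC-4532, in 8 conditions. Per the labels, cells grown through a second round of culture without zinc were the zinc-deficient state (0 h), and they were sampled again at 5 times after 2.5 µM zinc had been added, first at 1.5 h and last at 24 h. The remaining 2 conditions were zinc-replete cultures, named early and late in the labels. No condition received the same handling without zinc, and the labels do not say which replete culture matched the 0 h culture in age. Messenger RNA was selected and sequenced from a stranded library kit, per the labels' protocols.

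The deposited table gives FPKM, a fragment count scaled to transcript length and library size, per gene and condition, with a lower and an upper confidence bound and a status, per the file headers. TopHat2 and Cuffdiff were used, per the submitters' processing notes. Their versions, the genome build, the level of the confidence bounds and whether and how replicates were combined are not given in the sources used here. The design text names 4 biological replicates per condition, while the table holds 1 value per condition. Any combining of replicates therefore took place before the FPKM values were deposited. All 8 conditions were matched to their columns by name, and 0 columns of per-sample values were left unused. Coordinates are those of the table, written from 1, and a gene's span there can cover neighbouring models, since 380 genes shared their span with another gene. Gene symbols were those the table pairs with its identifiers (2756 of 17737 genes). A reference gene table (assembly Chlamydomonas_reinhardtii_v5.5) matched 11713 identifiers and held no symbols beyond locus tags, so genes with an identifier alone stay unnamed.

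The table holds no replicate values, so no p-value was computed and every call is a description of these deposited values. Ratios were computed as log2((a + 1)/(b + 1)), with a pseudocount of 1 FPKM, which understates the change of genes with low values. A gene was called higher or lower where the log2 ratio was at least 1 in size, the deposited bounds of both conditions did not overlap, both statuses were OK, and its mean FPKM over the 8 conditions was at least 1 (11498 genes). The words rose and fell are used of called genes only. The main deficiency result took genes called in the same direction against each replete condition, with the smaller of both ratios as their size. List medians for deficiency against both replete conditions used the mean of both log2 ratios instead, so they lie between the early and late values. In 9 genes, 18 values carried a status for too much data and are listed at 0. These are failed estimates, so such a condition was left out of the comparisons for that gene. The listed values of 0 still entered total FPKM, the equal-total factors and the mean over the 8 conditions.

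Recovery was 1 minus the log2 distance from the mean replete level at a given time over that distance at 0 h, in percent. A gene counted as back when it lay within 1 log2 unit of the range of both replete levels. Transient genes were called at 1.5, 3 or 4.5 h against 0 h and called in the opposite sense at 24 h against that time. All resupply comparisons share the 0 h value. Overlaps and transient counts were therefore set beside 100 simulated sets of unchanged conditions, drawn with the widths of the deposited bounds (taken as 2 SD on each side), and beside the overlap of independent lists. What the bounds hold is not known, and they can leave out variation between cultures, so the simulated counts can be too low and are no error rate for the calls.

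Gene lists were fixed before the data were examined. Of 32 lists, 4 matched no symbol in the table (COG0523 GTPases, autophagy, triacylglycerol and organelle-encoded genes). For 23 lists with at least 5 usable members, the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart where its median lay outside the range of its random lists left after 2.5% was cut from each side. Genes are not replicates, and these percentiles describe the deposited conditions only. The genes named in the text follow a rule fixed at the same time. For deficiency and for 1.5 and 24 h, it takes up to 4 called members each of the ZIP transporter, COG0523, copper, carbonic anhydrase and carbon concentrating lists, the 6 highest and 6 lowest called genes with a symbol, and up to 2 called members per direction of every other list that stood apart. For the other comparisons it takes the 3 highest and 3 lowest, and for transient genes the 4 highest and 4 lowest. Uncalled members of the first lists could be named with values. MTP1 in deficiency, CTR1, CTR3 and CAH7 at 1.5 h, LCI5 at 24 h, and the genes of the closing part were named outside this rule.

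Sequencing depth could not be recovered. Low FPKM values shared no common step between conditions (9.09% to 20.3% of the low-value ratios lay near their commonest value), so the deposited bounds give the precision. In the median gene the interval reached 16.2% to 31.0% to each side of the value, widest in the late replete condition. Closely similar gene copies, such as CAH4 and CAH5, CCP1 and CCP2, LHCSR2 and LHCSR3, and the LHCBM genes, are uncertain one by one, because fragments can be shared between them.

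The calling step was tested on simulated values with changed genes planted among 11459 tested genes. For deficient against early replete cells it recovered 100.0% of the genes changed 8-fold and 76.8% of those changed 3-fold, recovered 0 of 50 genes changed 1.5-fold, which lie below the threshold, and made 5 false calls. For deficient against both replete conditions it recovered 98.0% of the genes changed 8-fold, 70.7% of those changed 3-fold and 0 of 50 changed 1.5-fold, with 1 false call. Alternatives were a pseudocount of 0.1 or 5, no filter or a mean FPKM of at least 5, a fold threshold of 4 or 1.5, no condition on the bounds, rescaling by median-of-ratios factors, rescaling to the same total, and either replete condition alone as the reference for recovery. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.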

Results

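Messenger RNA of Chlamydomonas reinhardtii was measured in zinc-replete cells (early and late), in zinc-deficient cells, and in the same deficient cultures at 5 times after zinc had been returned. The comparisons ask which genes differ in zinc deficiency and how fast each returns once zinc is available. Each condition has 1 deposited FPKM value per gene with a confidence interval and no replicate values, so no difference below has a replicate check or a p-value. Between 11014 and 11554 genes had an FPKM of at least 1 in a condition. Total FPKM, with failed estimates counted as 0, ranged from 720944 at 0 h to 886096 in early replete cells.

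Zinc-deficient cells held higher levels of 4 zinc uptake transcripts, and 2 of these, ZRT1 and ZRT3, were nearly absent from replete cells. ZRT1, a transporter of the ZIP family of metal importers, stood at 313 FPKM (interval 233 to 393) at 0 h against 0.383 in early and 0.325 in late replete cells. ZRT3 stood at 103 FPKM against 0.144 and 0.135. ZRT2 and ZRT5 were also higher, at 104 FPKM against 6.92 and 3.83, and at 44.1 FPKM against 8.78 and 5.05. Of 12 tested members of this family, 4 were higher in deficiency, 0 were lower and 8 were not called, and the list median of 0.04 lay within the random range (percentile 69.5). IRT1, at 3.56 FPKM against 0.0454 and 0.00554, lay below the filter on mean level and was not called. ZRT4 was at 23.8 FPKM against 31.8 and 23.4, and was not called. The 4 higher members span 5608657 to 5616162 on chromosome 7 (ZRT1, Cre07.g351950), 1658225 to 1661356 on chromosome 13 (ZRT3, Cre13.g573950), 41896 to 46547 on chromosome 1 (ZRT2, Cre01.g000150) and 6052112 to 6056305 on chromosome 7 (ZRT5, Cre07.g355150), in a build not given in the sources used here. MTP1, a cation diffusion facilitator, was at 69.4 FPKM in deficiency against 8.61 and 8.17, and 3 other tested members of that family were not called.

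**Figure D1:**
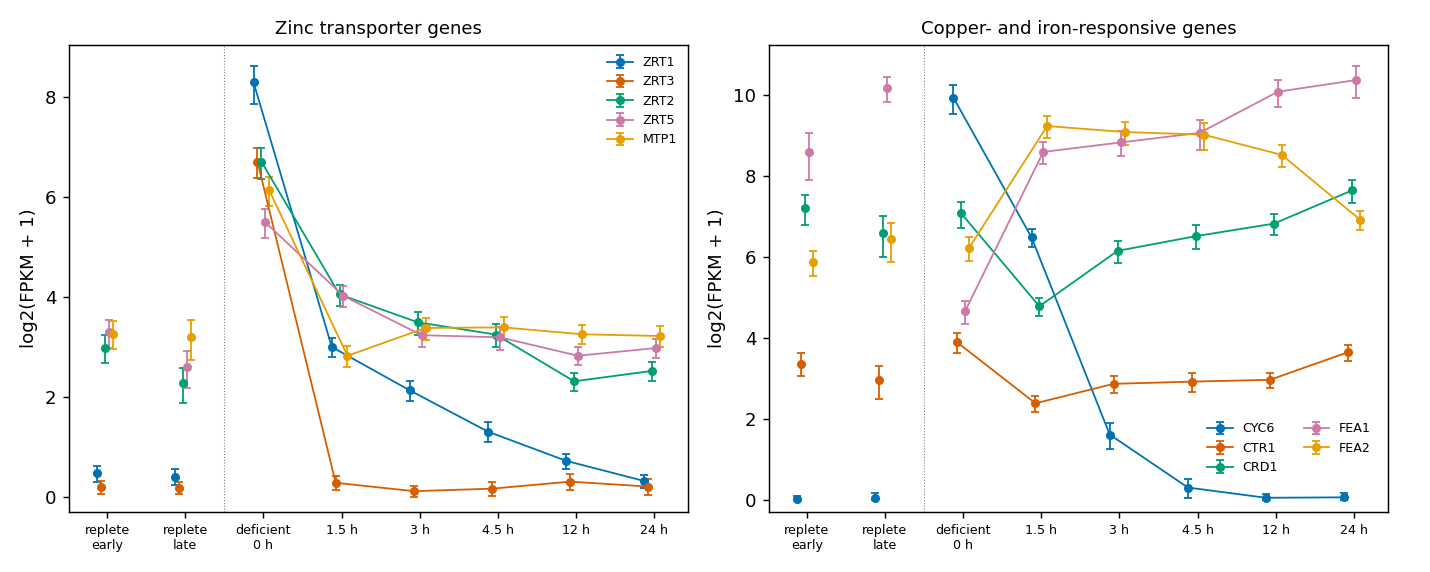
Expression of zinc transporter genes (left) and of copper- and iron-responsive genes (right) in the 8 conditions, as log2(FPKM + 1) on the vertical axis. Points are deposited values, bars their deposited intervals, lines join 0 h and the resupply times, and the horizontal axis lists conditions in order and is not to scale. ZRT3 went from 103 FPKM at 0 h to 0.214 at 1.5 h.

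Some copper genes and several iron genes differed as well. CYC6, the cytochrome that replaces plastocyanin when copper is short, stood at 976 FPKM in deficiency (interval 732 to 1220) against 0.0139 and 0.0372 in replete cells, the highest ratio among called genes with a symbol (log2 ratio at least 9.88 against each). HMA1, a metal-transporting ATPase, and CTR2, a copper transporter, were higher too, at 15.9 FPKM against 4.19 and 3.12 and at 12.9 FPKM against 5.21 and 3.13. The other 10 of 13 copper genes were not called and the list median of 0.23 lay within the random range (percentile 95.1), as it did against early replete cells alone (0.19), while it was 0.86 against late ones (percentile 100.0). Among the uncalled genes was the regulator CRR1 at 30.2 FPKM against 37.4 and 34.1. In contrast, 3 of 6 tested iron genes were lower, 0 were higher, and the list median of -1.48 lay at the 0.1 percentile of random lists. FEA1, a secreted iron-assimilation protein, was at 24.2 FPKM (interval 19.2 to 29.2) against 385 and 1152, and TEF22, its neighbour, was at 11.4 FPKM against 41.4 and 75.2.

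Many genes of growth and photosynthesis were lower in deficient cells. Of 26 tested genes of the cell cycle and DNA replication, 19 were lower and 0 were higher, with a median log2 ratio of -1.81 (percentile 0.0), and RIR2, a subunit of ribonucleotide reductase, was at 2.98 FPKM against 44.3 and 59.9. CYCA1, a cyclin, was at 1.83 FPKM against 23.1 and 29.7. Light-harvesting genes were lower in 9 of 14 tested members (median -1.36), including LHCBM4 at 198 FPKM against 1843 and 1461 and LHCA6 at 486 FPKM against 1817 and 1697. Acetate and glyoxylate genes were lower in 7 of 13 (median -1.37), led by ICL1, isocitrate lyase, at 191 FPKM against 2707 and 3082, and by ACS3, an acetyl-CoA synthetase, at 50.7 FPKM against 458 and 675. Tetrapyrrole genes were lower in 4 of 11 (median -1.09; GUN4 and PPX1 among them), photosystem genes in 3 of 12 (median -0.94; PSAG and PSBP1), and plastid ribosomal protein genes in 2 of 32 (median -0.83; PRPS10 and PRPL7). None of these 3 lists had a higher member. The plastid ribosomal list depended on the reference, with 22 of 32 lower against early replete cells (median -1.12) and 2 of 32 against late ones (median -0.57), and tetrapyrrole genes were lower in 7 and 4 of 11. Cytosolic ribosomal protein genes gave 1 higher and 0 lower among 51, the higher one being RPS27e2 at 84.0 FPKM against 10.4 and 23.5. Their median of 0.02 lay above the range of random lists of like expression (-0.62 to -0.16).

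Stress-linked light-harvesting proteins went both ways. LHCSR2 and LHCSR3, photoprotective antenna proteins, were higher at 66.1 FPKM against 3.36 and 1.62 and at 58.6 FPKM against 3.21 and 3.65, while LHCSR1 was lower at 0.568 FPKM against 20.9 and 10.8. The other 4 members of that list were not called, and its median of 0.61 lay at the 98.6 percentile. Small heat shock proteins HSP22E (1121 FPKM against 139 and 92.3) and HSP22F (553 FPKM against 83.1 and 54.5) were among 4 higher genes of 32 chaperones, with 0 lower. Starch genes split 1 and 1 of 11, with SSS1 higher and SSS2 lower, while their list median lay outside the random range. Flagellar genes gave 2 higher (FAP280, BBS3B) and 4 lower (FAP35 and FAP40 among them) of 255, and their list median also lay outside the random range. Carbonic anhydrases, which are zinc enzymes, gave CAH2 lower at 1.54 FPKM against 20.3 and 14.8, CAH4 higher at 76.3 FPKM against 30.0 and 14.7, and 9 not called. In the carbon concentrating list CCP2 and NAR1.2 were higher, and LCI5 and LCIC were among 3 lower genes, of 9 tested. This list depended on the reference, with 2 higher and 4 lower against early replete cells (median -0.33, within the random range) and 5 higher and 3 lower against late ones (median 1.65, percentile 100.0).

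Other lists showed few calls against both replete conditions. Superoxide dismutases gave 0 higher and 1 lower of 4, antioxidant enzymes 3 higher and 2 lower of 21, phosphate and sulfate genes 3 higher and 1 lower of 14, fermentation genes 1 higher and 0 lower of 12, mitochondrial ribosomal genes 1 higher and 0 lower of 37, and the 2 gamete genes past the filter 0 higher and 1 lower. Proteasome, nitrogen assimilation, FTSH and methionine genes had 0 calls among 21, 8, 4 and 1 tested. The 8 histone genes past the filter had 0 calls and a median of 0.99, which was -0.05 over all histone genes without the filter, and 5 of them were higher against late replete cells alone. Against early replete cells alone 4 starch genes were higher. The remaining genes at the extremes were SLT1, a sulfate transporter (218 FPKM against 1.69 and 1.14), AOT4 (110 FPKM against 2.95 and 1.65) and LZY1B (184 FPKM against 6.47 and 5.13) on the higher side, and PHC18, a pherophorin (0.0292 FPKM against 402 and 231), FMG1-B, a flagellar membrane glycoprotein (1.85 FPKM against 68.1 and 79.5), TRP5, an ion channel (0.0296 FPKM against 14.4 and 14.5), and RBD2 (56.5 FPKM against 695 and 665) on the lower side.

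Over all genes, 639 were higher and 660 lower in deficiency against both replete conditions, of 11451 tested. Simulated unchanged conditions gave 3.47 calls on average and 10 at most, a count that holds only the spread within the deposited bounds and can be too low. Against the early replete condition alone 870 were higher and 1011 lower, and against the late one 857 and 876. The 3 highest and 3 lowest named genes were CYC6, ZRT1 and ZRT3, and PHC18, FMG1-B and FEA1, against the early condition, with SLT1 in place of ZRT3 against the late one. A fold threshold of 4 left 306 genes and a pseudocount of 5 left 675, while rescaling to the same total gave 778 higher and 513 lower against both, and 1318 higher and 624 lower against the early condition, where median-of-ratios factors gave 957 and 929. CTR2, SSS1, PPX1 and FAP40 lost their call with a pseudocount of 5, CTR2, FAP40, TRP5 and LHCSR1 with a mean FPKM of at least 5, PRPL7 with either rescaling, and LCIC and PSBP1 with the equal total.

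The genes called between the early and late replete cultures were a small set that includes low-CO2 genes, while several lists shifted with few calls. CAH1, the periplasmic carbonic anhydrase, was at 548 FPKM (interval 322 to 774) in early and 8.10 FPKM in late cells, LCI1, a low-CO2 inducible membrane protein, at 29.8 and 0.140 FPKM, and NAR1.2, a chloroplast anion transporter, at 19.7 and 3.07 FPKM. Of 9 carbon concentrating genes, 5 were lower in late cells and 0 higher (median -1.24, percentile 0.0), as were 2 of 11 carbonic anhydrases. Medians also lay below the random range for plastid ribosomal (-0.50), mitochondrial ribosomal (-0.39), copper (-0.39) and histone (-0.39) genes. Among these lists 1 copper gene was called lower and no other gene was called. The cell cycle median of 0.26 lay above its random range, with 0 calls. FRE1, a ferrireductase, was higher in late cells at 7.32 against 0.418 FPKM, as were AMX2 (7.96 against 0.682 FPKM) and TBA1 (80.6 against 17.3 FPKM), and 2 of 6 iron genes were higher. In total 85 genes were higher and 79 lower in late cells, of 11465, against 11.8 calls on average in simulated unchanged conditions. The split was 172 higher and 28 lower after rescaling to the same total, a mean FPKM of at least 5 ended the calls of FRE1 and AMX2, and the total was 316 with a pseudocount of 0.1, 53 with 5, and 11 at a fold threshold of 4.

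At 1.5 h after zinc addition the zinc uptake genes raised in deficiency had already fallen, and genes for plastid ribosomal proteins and several iron and low-CO2 genes had risen. ZRT3 fell from 103 to 0.214 FPKM, within the interval of early replete cells (0.0369 to 0.251), and ZRT1 fell from 313 to 7.00 FPKM. ZRT2 fell to 15.6 and ZRT5 to 15.2 FPKM, and MTP1 fell to 6.08 FPKM. Of 12 ZIP family members, 5 were lower than at 0 h and 0 were higher. CYC6 fell from 976 to 88.1 FPKM.

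Other copper genes fell beside CYC6. Of 13, 7 were lower, 0 higher and 6 not called at 1.5 h (median -1.13, percentile 0.0), including CTR2 from 12.9 to 0.906 FPKM, CRD1, a cyclase subunit of chlorophyll synthesis, from 134 to 26.4 FPKM, and CPX1, coproporphyrinogen oxidase, from 178 to 45.4 FPKM. CTR1 and CTR3 fell from 13.8 to 4.20 and from 23.5 to 9.16 FPKM. At these levels CTR2, CRD1 and CPX1 were below their replete values (CTR2 at 5.21 and 3.13, CRD1 at 146 and 95.4, CPX1 at 147 and 97.8 FPKM). Iron genes rose in 4 of 6 (median 1.97, percentile 100.0). FEA1 rose from 24.2 to 384 FPKM and FEA2 from 73.5 to 599 FPKM, the latter above both replete values of 57.2 and 85.4.

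All 32 nuclear genes for plastid ribosomal proteins rose by 1.5 h, and all 32 were also called at 3 and 4.5 h. Their median log2 ratio was 1.61 at 1.5 h, 1.88 at 3 h and 1.63 at 4.5 h, each at the 100.0 percentile. PRPS10 went from 168 to 746 FPKM and PRPL17 from 140 to 564 FPKM. Cytosolic ribosomal protein genes gave 1 higher and 1 lower of 51, and mitochondrial ones 1 and 1 of 37. Chaperones gave 10 higher and 5 lower of 32, with a median within the random range.

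Of 9 carbon concentrating genes, 6 rose and 0 fell (median 1.71, percentile 100.0). LCI1 rose from 2.59 to 98.8 FPKM, CCP1 from 30.0 to 155 FPKM, NAR1.2 from 49.1 to 246 FPKM and CCP2 from 54.4 to 204 FPKM. Among 11 carbonic anhydrases, CAH5, CAH1, CAH2 and CAH4 rose, CAH7 fell from 22.4 to 8.55 FPKM, and 6 were not called. CAH1 rose from 286 to 1135 FPKM. Nitrogen genes rose in 4 of 8 (median 0.95; AMT7, an ammonium transporter, from 11.1 to 44.0 FPKM, and AMT6), and phosphate and sulfate genes in 5 of 14 with 1 lower (median 0.76; PTB4 and PTB2 higher, SLT1 lower).

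Most fermentation genes and some proteasome and antioxidant genes fell at 1.5 h. HYDA1, a hydrogenase, fell from 146 to 10.2 FPKM and ADH1, an alcohol dehydrogenase, from 187 to 38.1 FPKM, and 8 of 12 fermentation genes were lower with 0 higher (median -1.30). Proteasome genes were lower in 9 of 21 (median -0.93; RPN10 and POA1), antioxidant genes in 6 of 21 (median -0.35; APX1 and MSRA5), starch genes in 5 of 11 (median -0.62; SSS3, Cre06.g282000, and SBE3) and superoxide dismutases in 3 of 4, with 0 higher in each. Flagellar genes gave 24 lower (IFT25, FAP291 among them) and 2 higher (FAP224, FAP211) of 255. HTA38 was the 1 histone gene of 8 that rose, from 1.66 to 4.53 FPKM, and its call ended with both rescalings. Cell cycle genes gave 1 higher and 0 lower of 26, light-harvesting genes 0 higher and 2 lower of 17, tetrapyrrole genes 1 and 0 of 11, acetate genes 1 and 1 of 13, photosystem and FTSH genes 0 of 12 and 0 of 4.

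In total 1371 genes rose and 1059 fell at 1.5 h, of 11463 tested, against 4.16 calls on average in simulated unchanged conditions. The balance turned to 1241 and 1255 with median-of-ratios factors and to 1246 and 1304 at equal totals. The highest with a symbol were LCI1, FEA1, PRM1 (22.1 to 237 FPKM), THIC, an enzyme of thiamine synthesis (6.16 to 67.8 FPKM), PRL10 (0.548 to 13.7 FPKM) and PUF1 (9.46 to 86.3 FPKM), and the lowest were ZRT3, ZRT1, HYDA1, TBA1 (30.1 to 1.51 FPKM), CYC6 and MTP1. Of the genes that rose, 1250 (91.2%) were not among the genes called in deficiency, and of those that fell, 719 (67.9%) were not. Only 11.3% of all genes tested for deficiency were called there, so the 91.2% is near the share over all genes. A pseudocount of 5 left 1291 calls and a fold threshold of 4 left 448. CAH2, AMT6 and HTA38 lost their call with a pseudocount of 5, and AMT6, CTR2 and HTA38 with a mean FPKM of at least 5.

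At 3 and 4.5 h many cell cycle and chlorophyll synthesis genes were higher as well. Cell cycle genes were higher in 14 of 26 at 3 h and 20 of 26 at 4.5 h (medians 1.01 and 1.46), after 1 at 1.5 h, and tetrapyrrole genes in 8 and 10 of 11 (medians 1.53 and 1.88). Acetate genes were higher in 7 of 13 at both times. Carbon concentrating genes were higher in 2 of 9 at 3 h (median 0.28, within the random range) and 5 of 9 at 4.5 h (median 1.11, percentile 99.5). Among called genes with a symbol, LCI1, THIC and FEA1 were the highest at both times, THIC reaching 158 FPKM at 3 h and LCI1 192 FPKM at 4.5 h, and CYC6, ZRT3 and ZRT1 the lowest, CYC6 at 2.05 and 0.230 FPKM. In total 1188 genes rose and 665 fell at 3 h, and 1171 and 747 at 4.5 h. The split depended on scaling: after median-of-ratios rescaling it was 912 and 868 at 3 h and 887 and 905 at 4.5 h, and at equal totals 759 and 1065, and 741 and 1044.

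By 12 h light-harvesting genes had risen in 13 of 14 tested members (median 1.44, percentile 100.0) and photosystem genes in 9 of 12 (median 1.09). Iron genes were higher in 6 of 6, and FEA1 reached 1079 FPKM. Plastid ribosomal genes were called in 7 of 32. Carbon concentrating genes gave 4 higher and 1 lower of 9 (median 0.28, within the random range). FEA1, LCI1 (97.6 FPKM) and CAH2 (31.3 FPKM) were the highest and CYC6 (0.0323 FPKM), ZRT1 (0.646 FPKM) and ZRT3 (0.235 FPKM) the lowest called genes with a symbol. In total 831 genes rose and 723 fell, and the balance turned to 780 and 820 at equal totals. A fold threshold of 4 left 297 calls at this time.

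At 24 h the deficiency pattern was largely undone, while several low-CO2 genes were lower than at 0 h. ZRT1 was at 0.244 FPKM, ZRT3 at 0.152, ZRT2 at 4.74 and ZRT5 at 6.88, and CYC6 at 0.0402. HMA1 and CTR2 were lower than at 0 h, and CTP2, a copper-transporting ATPase, was higher at 10.5 against 4.27 FPKM, in a copper list with 1 higher and 3 lower of 13. FEA1 reached 1318 FPKM (interval 968 to 1668) and TEF22 109 FPKM, with 5 of 6 iron genes higher (median 2.55). Cell cycle genes were higher in 19 of 26 (median 1.39; RIR2 and CYCA1, the latter at 18.3 FPKM), light-harvesting genes in 12 of 14 (median 1.46; LHCBM4 at 1852 and LHCA6 at 2061 FPKM), tetrapyrrole genes in 7 of 11 (median 1.40; GUN4, GSA1), acetate genes in 8 of 13 (median 1.28; ICL1 at 2976 and ACS3 at 589.6 FPKM), plastid ribosomal genes in 16 of 32 (median 1.01; PRPL7, PRPS10) and photosystem genes in 6 of 12, with 0 lower in each.

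In the carbon concentrating list 5 of 9 genes were lower than at 0 h and 1, LCI5, was higher (median -1.43, percentile 0.0), with NAR1.2 at 1.53, CCP2 at 4.72, CCP1 at 5.34 and LCR1, a low-CO2 regulator, at 1.00 FPKM. CAH1 fell to 11.3 FPKM, CAH4 to 13.3 and CAH5 to 6.25 FPKM, and CAH2 was higher at 21.3 FPKM. In the late replete culture CAH1 was at 8.10, CAH4 at 14.7 and CAH5 at 7.59 FPKM, while CAH2 was at 14.8 there and at 20.3 FPKM in the early one, and NAR1.2 at 24 h lay below its late replete interval (2.03 to 4.11 FPKM). Chaperones gave 2 higher (CPN60A, CPN60B2) and 4 lower (HSP22E and HSP22F among them) of 32, histones 0 and 2 of 8 (HBV1, HTB38), starch genes 1 and 0 of 11 (SSS2; list median -0.45, percentile 1.30), flagellar genes 5 and 2 of 255 (FAP269 and FAP35 higher, FAP280 and BBS3B lower), and RPS27e2 was lower at 13.4 FPKM.

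**Figure D2:**
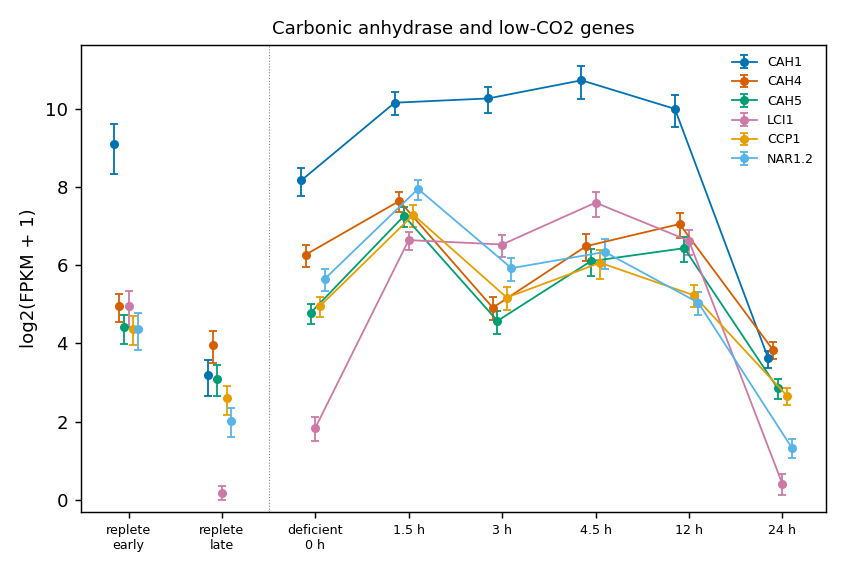
Expression of carbonic anhydrase and low-CO2 genes in the 8 conditions, as log2(FPKM + 1) on the vertical axis, with conditions in order and not to scale on the horizontal axis. Points are deposited values, bars their deposited intervals, and lines join 0 h and the resupply times. CAH1 was at 1017 FPKM at 12 h and 11.3 FPKM at 24 h.

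In total 973 genes rose and 793 fell at 24 h against 0 h. Beside those above, the extremes among called genes with a symbol were HRP3 (1.64 to 33.0 FPKM), FMG1-B (1.85 to 34.5 FPKM) and RBD2 on the higher side, and SLT1 (218 to 1.45 FPKM), LHCSR2 (66.1 to 0.523 FPKM) and SLT2, another sulfate transporter (219 to 6.38 FPKM), on the lower side. Rescaling to the same total gave 766 higher and 1025 lower, median-of-ratios factors gave 875 and 903, and a fold threshold of 4 left 343 calls. CTP2, CTR2, HTB38, HBV1, CPN60A and LCR1 lost their call with a pseudocount of 5, CTR2 and HTB38 with a mean FPKM of at least 5, CPN60A and CPN60B2 with either rescaling, and CTP2 with the equal total.

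At 1.5 and 3 h, genes that were higher in deficiency had returned further than genes that were lower. The medians were close at 4.5 h and in the reverse order at 12 h. A deviation of the 1.5 h values beyond their deposited bounds cannot be told apart from the early gap. Among the higher genes, the median return at 1.5 h was 57.9% of the log2 distance (quartiles 31.5% and 82.4%), and among the lower genes it was 10.3% (quartiles -6.45% and 46.7%). The latter depended on settings: it was 20.4% with a pseudocount of 0.1, 20.9% at a fold threshold of 1.5, 19.7% with a mean FPKM of at least 5, 6.07% and 5.97% after the rescalings and 2.95% at a fold threshold of 4. Medians then went to 66.2%, 77.3%, 90.1% and 98.0% for the higher genes and to 50.6%, 74.8%, 94.1% and 93.8% for the lower genes at 3, 4.5, 12 and 24 h. At 24 h, 631 of 639 higher and 632 of 660 lower genes were within 1 log2 unit of the range of both replete levels. This bar equals the distance at which genes were called, so a small shift can meet it. At 1.5 h, 434 of 638 higher and 231 of 660 lower genes already did. With no true return, selection on the 0 h value gave 1.21% to 1.68% in simulation. That simulation took the observed 0 h values as true and its spread from the deposited bounds alone, so these percentages can be too low.

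**Figure D3:**
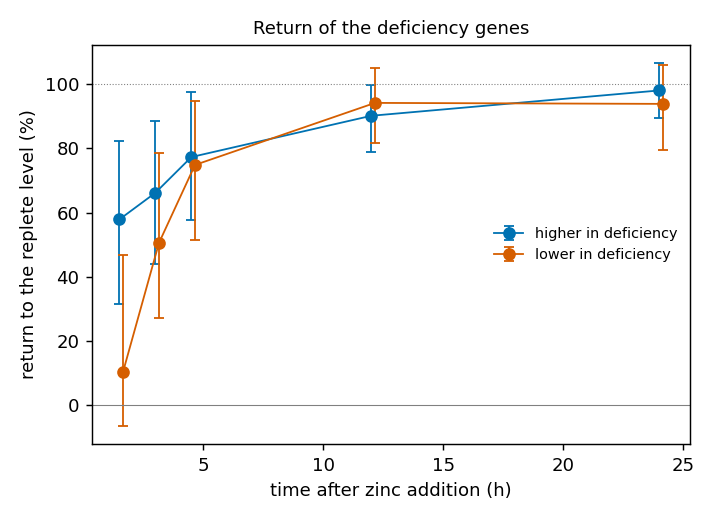
Return of the genes called in deficiency toward the mean replete level, in percent of the log2 distance at 0 h, against hours after zinc addition. Points are medians over 639 higher and 660 lower genes, and bars span the quartiles over genes. At 1.5 h the medians were 57.9% and 10.3%.

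Of the 638 higher genes tested at 1.5 h, 320 were called lower than at 0 h, and at 24 h 584 of 639 were. Of the 660 lower genes, 114 were called higher at 1.5 h and 577 at 24 h. Simulated unchanged conditions shared 1.17 and 2.99 in all at those times, but they made only 3.47 deficiency calls on average. Their overlap could therefore not be large, and it does not measure the effect of the shared 0 h value. Independent lists would share 58.9 and 44.2 of the higher and 79.1 and 56.1 of the lower genes. Since every comparison uses the same 0 h value, which cannot be split, part of the excess may come from it. Across all 5 times 155 genes were higher and 313 lower than at 0 h.

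Many genes called early were called in the opposite sense between that time and 24 h, in 2 comparisons that share the early value. There were 711 transient genes that rose and 431 that fell, of which 691 and 411 were called at 1.5 h, against 0.01 and 3.48 on average in simulated unchanged conditions. A deviation of the 1.5 h value beyond its deposited bounds would produce both calls and cannot be told apart here. Among the genes that rose were LCI1, THIC, PRM1 and PUF1, and among those that fell TEF13 (139 FPKM at 0 h, 5.59 at 3 h, 107 at 24 h), GOX17 (42.2, 1.14 at 4.5 h and 4.66 FPKM), HYDA1 and TBA1. Such a gene need not be back at its 0 h level, as THIC was still called higher at 24 h than at 0 h (log2 ratio 2.97) and HYDA1 lower (-1.05). Among them 14 and 37 were deficiency genes, a number kept low by the definition, since a gene that returns and stays at the replete level does not meet it. A fold threshold of 4 left 69 transient genes, with 23 higher and 46 lower, and without the 1.5 h condition 229 remained, an alternative chosen after seeing the data.

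**Figure D4:**
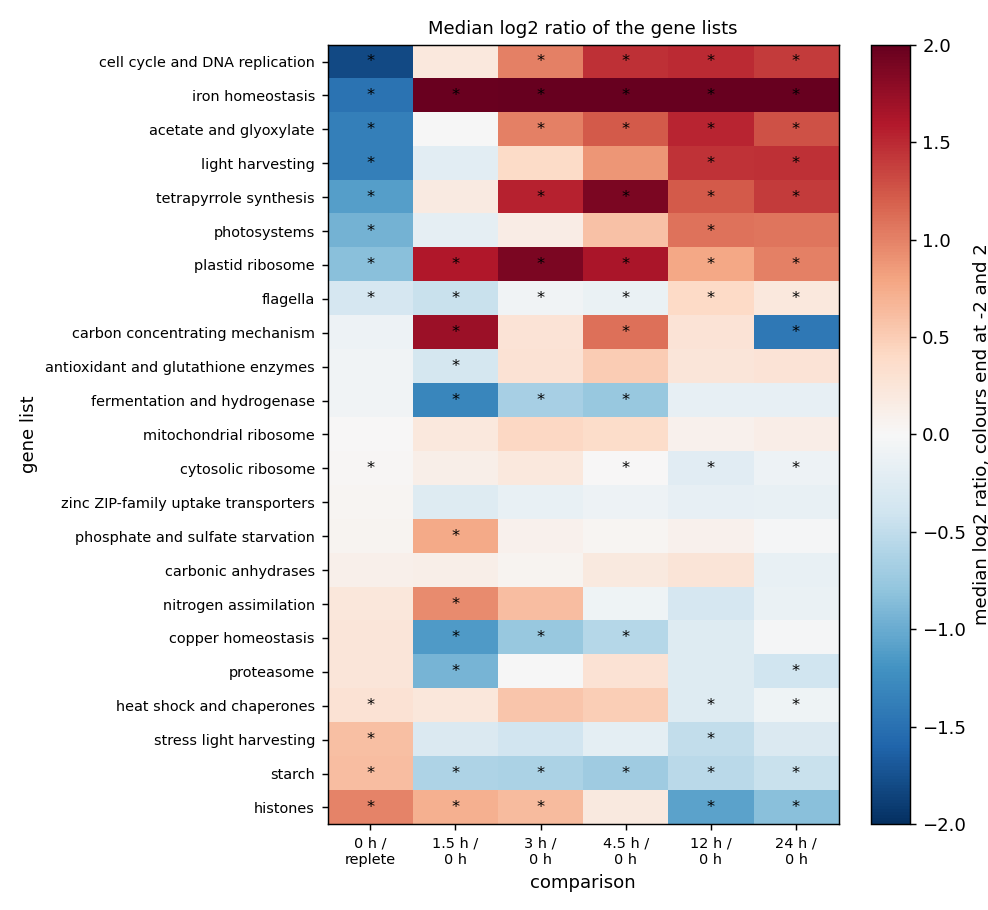
Median log2((FPKM + 1) ratio) of the 23 gene lists with at least 5 usable members, with lists on the vertical axis and comparisons on the horizontal axis. Colours show the median, and an asterisk marks a median outside the range of matched random lists left after 2.5% was cut from each side. Over all 9 comparisons, some of them not drawn, 112 of 207 medians lay outside. If list members varied independently, 10.4 would, but members of a list can vary together and the comparisons share values. The plastid ribosome list stands at 1.61 at 1.5 h.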

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

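The tests of culture stage and of zinc sufficiency below were chosen after the levels of these genes had been seen.

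A total of 2 genes were called in opposite directions against the early and the late replete conditions, and the difference was not tested. LCI1 had a log2 ratio of -3.10 in deficient against early and 1.65 against late replete cells. The gene g15294 had -1.57 and 1.25.

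A total of 38 genes were called in opposite directions at 1.5 and 24 h against 0 h, a difference between times that was not tested. The log2 ratios at 1.5 and 24 h were 4.80 and -1.43 for LCI1, 1.89 and -3.28 for CCP2, 1.98 and -4.55 for CAH1, 2.33 and -2.29 for CCP1, 1.37 and -2.44 for CAH4, 2.48 and -1.93 for CAH5, and 2.30 and -4.30 for NAR1.2. LHCBM4 and FAP35 went the other way, at -1.21 and 3.22 and at -1.14 and 2.03.

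The gene Cre07.g352000 lies next to ZRT1 on chromosome 7, and its 0 h estimate failed, so no comparison with 0 h includes it. It stood at 542 FPKM at 1.5 h against 2.49 and 1.84 FPKM in early and late replete cells, and was at 54.2, 13.2, 2.52 and 2.49 FPKM at 3, 4.5, 12 and 24 h.

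Among the carbonic anhydrase and carbon concentrating genes, 9 were called lower at 24 h than at 12 h. Under both rescalings 100.0% of these genes kept the call. The factors were larger at 24 h than at 12 h (0.995 against 0.968 and 1.00 against 0.935), so each lowered the 24 h ratios further. The kept calls were therefore fixed in advance and do not decide on library scaling. Zinc sufficiency as the whole cause is argued against, since 7 of the 9 genes were called higher in early replete cells than at 24 h. Culture stage may account for the drop as a hypothesis: 77.8% of the 9 genes were also called lower in late than in early replete cells, and of 43 other genes lower at 24 h than at 12 h, 4 were also lower in late replete cells where independent lists would share 0.271. In the other direction 2 of 24 genes were shared (0.178 expected), and 3 of the genes higher and 2 of those lower at 24 h were called in the opposite sense in late replete cells. The protocol gives the density at zinc addition, while the densities at later times and in the replete cultures and the carbon supply are not given in the sources used here, and the same values raised and tested this explanation.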

How the results depend on the processing

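The alternatives that left out genes called between the replete conditions, genes that share a span, or the 1.5 h condition were chosen after seeing the data. With 1 value per condition no replicate could be left out, and no paired analysis was possible because the columns carry no replicates. Counts of calls moved with thresholds, as built: stricter rules make fewer calls.

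In the order deficient against early, late and both replete, late against early replete, each resupply time against 0 h from first to last, and transient genes, the calls were 940, 854, 675, 53, 1291, 992, 951, 797, 897 and 559 with a pseudocount of 5. At a fold threshold of 4 they were 369, 411, 306, 11, 448, 237, 242, 297, 343 and 69, and at 1.5 they were 3945, 3303, 2594, 680, 4750, 4002, 4002, 3479, 3838 and 2875. With a pseudocount of 0.1, late against early replete gave 316 and transient genes 1716. With a mean FPKM of at least 5, deficient against late gave 1117 and against both 848, where fewer genes were tested. Without the 1.5 h condition 229 genes were transient. All other totals of calls stayed within 1.5 times of those reported. The split into higher and lower genes moved further at equal totals, as from 85 and 79 to 172 and 28 in late against early replete. The median return at 1.5 h became 20.4% for lower genes with a pseudocount of 0.1 and 20.9% at a fold threshold of 1.5, 19.7% for them with a mean FPKM of at least 5, 6.07% and 5.97% with median-of-ratios factors and equal totals and 2.95% at a threshold of 4, and 47.0% for higher genes at a threshold of 4, and the cause was not tested.

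Rescaling to the same total moved the median log2 ratio of all genes by 0.23 in deficient against early replete, 0.12 against both, 0.22 in late against early replete, and -0.22, -0.18 and -0.12 at 3, 4.5 and 24 h. Median-of-ratios rescaling moved it by -0.13 at 3 h and -0.11 at 4.5 h. Without the filter, the median of the histone list reversed against early, late and both replete (-0.0507, -0.0292 and -0.0512) and at 12 h (0.0289), and was 0.00 at 24 h, since this adds many histone genes with low values. Of 112 list medians outside their random range, 45 moved at equal totals, 41 with a pseudocount of 5, 25 with 0.1, 18 with a mean FPKM of at least 5, 14 without the filter and 7 with median-of-ratios factors. Reversal was counted only for the 76 medians of at least 0.5 in size, and among them none but the histone medians reversed. A change of sign in a smaller median was not counted as a reversal. None of the 172 ratios of named genes reversed, and 54 lost their call at a threshold of 4. The depth behind each value is unknown, so precision can be judged from the deposited intervals alone. The condition on them decided few calls. Without it, deficient against both replete gave 1304 calls in place of 1299, and 1.5 h against 0 h gave 2432 in place of 2430. The fold threshold therefore set nearly all calls.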

Other observations

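The tests below on library scaling, on gene level and span, and on low expression were chosen before their results were seen, and the statement on handling after. The genes in this part were picked after their values had been seen.

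Some deficiency genes had not returned by 24 h. Against both replete conditions, 28 of the 660 lower genes were still lower at 24 h and 6 of the 639 higher genes still higher. PHC18 was at 8.06 FPKM at 24 h against 402 and 231 in replete cells, and TRP5 at 0.970 FPKM against 14.4 and 14.5. Both genes of the flagellar membrane glycoprotein differed in opposite ways: FMG1-B was lower in deficiency, while FMG1-A stood at 7.07 FPKM at 0 h, 60.4 at 12 h and 38.9 at 24 h against 0.401 and 0.614 in replete cells. Of 12 pherophorin genes tested, 3 were lower in deficiency (PHC5, PHC15 and PHC18), 0 were higher, and 5 were higher at 24 h than at 0 h. PHC5 and PHC15 were not among the genes still lower at 24 h. MSD3, a manganese superoxide dismutase, was at 2.50 FPKM at 0 h against 19.2 and 16.0, stayed at 2.74 at 4.5 h and reached 17.6 at 12 h.

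Some of the strongest deficiency genes carry no symbol in the table. The gene g15199 (chromosome 14, 3509515 to 3515737) stood at 476 FPKM at 0 h against 0.0979 and 0.104, and at 1.80 FPKM at 1.5 h. Cre02.g118400 (chromosome 2, 6742697 to 6747622) stood at 394 FPKM against 0.0502 and 0.148, and at 9.68 FPKM at 1.5 h. On the lower side, Cre09.g398450 was at 0.107 FPKM against 83.5 and 64.7, and Cre14.g613800 at 0.375 FPKM against 76.2 and 66.6.

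All 32 plastid ribosomal protein genes rose at 1.5 h. Library scaling is argued against, since the list median was at least 1.49 under both rescalings and all 32 stayed called. A trend with level and gene span is argued against, since the median residual after removing it was 1.47 over 31 genes. The effect of zinc cannot be told apart from handling or elapsed time, because 0 of the 8 conditions had the handling without zinc. What set off the rise therefore stays open.

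Genes higher in deficiency were 47.5 percentage points further back at 1.5 h than genes lower in deficiency. The gap was at least 50.5 points under both rescalings. Their factors were larger at 1.5 h than at 0 h (1.02 against 0.949 and 0.977 against 0.901), a shift that by itself widens the gap. The rescalings therefore do not decide on library scaling. Low expression and the pseudocount are argued against as the whole cause, since the gap was at least 34.6 points with a mean FPKM of at least 5 or another pseudocount. What set the gap stays open.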
